A study of Nicotiana tabacum with 2 samples.

How the data were processed

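RNA of tobacco seedlings was sequenced in 2 libraries, 1 of control seedlings and 1 of seedlings on low potassium medium. The labels describe whole seedlings of Nicotiana tabacum, while the extraction protocol in the same labels names roots of another plant, alligator weed. The data bear on this: 4062 assembled transcripts had a best match in Nicotiana tabacum, at a median identity of 98.9% of aligned residues. Best matches in Nicotiana made up 9.33% of the annotated contigs, and the median identity over all matches was 82.9%. Among the transcripts, those of photosynthesis were among the most abundant. Whether the 3 treatment times were pooled before sequencing, and at what times control seedlings were taken, is not given in the sources used here.

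Per the deposited description, the authors trimmed low-quality ends and removed short (under 20 nt), empty and noncoding reads with fastx 0.0.13. They pooled the reads of both libraries and assembled them de novo with CLC Genomics Workbench 5.5. The read mapper and its treatment of reads with several matches are not given in the sources used here. No genome was used, so unigenes have no genomic position here, and near-identical copies (tobacco carries related copies of most genes) can share or split reads. The deposited expression table gives, per the file headers, whole read counts per unigene, unigene length in bases and RPKM (reads scaled by unigene length and by the reads of the library). Its reads, lengths and RPKM give 1 library total per column, 54827386 reads in the control and 43887023 in the low potassium library, and these totals were used. Protein descriptions come from the authors' search of UniProt 2012.05, deposited with a score (BLAST expectation value, at most 1e-05) and the aligned and identical residues; 43631 of the 64727 unigenes compared had one. The authors' deposited comparison lists RPKM values, the log2 ratio of control over low potassium, a p-value and a false discovery rate. The deposited description names Fisher's test on RPKM for it, and also DEGseq.

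The expression table holds 65535 unigenes and, with its header, as many lines as an old worksheet format allows (65536). It ends at contig 74379, whereas the annotation names contigs up to 146223. The library totals exceed the sums of the table by 1398643 control and 1352152 low potassium reads. The deposited RPKM formula words the total as assembly reads, but whether all of the excess lies on contigs outside the table was not tested. Counts of higher and lower unigenes therefore describe the table and not the whole assembly.

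For each unigene the log2 ratio of low potassium over control was computed from reads with 1 read added in each library, divided by the library total. Unigenes with fewer than 20 reads over both libraries were left out. A 2-fold difference is a rule of size, not a test, since 1 library per group allows no test between conditions. Printed folds are ratios of RPM (reads scaled to the library total) without the added read, with exact conditional binomial (Clopper-Pearson) 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules, and they hold nothing of the spread between plants. A transcript with 0 reads was set against a floor of 3 reads, which is 0.0547 RPM in the control and 0.0684 in the low potassium library. The median unigene had 212 control reads and 176 low potassium reads.

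Before the data were examined, 28 gene lists were fixed as word patterns on the protein descriptions. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and a percentile under 2.5 or over 97.5 was called standing apart. This describes these 2 libraries. Members of a list include near-identical unigenes, so percentiles overstate how far a list stands apart. The word patterns took in 6 rectifying potassium channels in the jasmonate list and 1 resistance protein in the auxin list; the lists were kept, and versions without them were run. The genes named were set by a rule of the same date: among unigenes with an informative description and at least 50 reads, taking the most abundant unigene per protein match, the 12 highest and 12 lowest ratios, up to 2 members at each end of every list among those at least 2-fold apart, every potassium transport unigene at least 2-fold apart, whatever its number of reads among those compared, and the 4 most abundant members of that list, and the 5 largest differences on each side of the authors' deposited table. The rule gave 112 unigenes from the expression table, of which the text names a part, chosen with the values in view; 1 that the rule selects is not reported here. Further genes were named after their values were seen, where the text says so.

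Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with edgeR 4.0.16 for TMM (trimmed mean of M values) factors and DESeq2 1.42.0 for median-of-ratios size factors, in R 4.3.3. TMM moved all log2 ratios by -0.08, and the size factors by -0.08. The methods were tested on simulated counts drawn from the real means and library totals of 65535 unigenes. With counting error alone, 232 of 64603 simulated unigenes were at least 2-fold apart. Of 200 unigenes changed 4-fold, 100% were recovered in the right direction, and 74.5% of 200 changed 2-fold passed 0.9 on the log2 scale. The 95% intervals held the true ratio in 95.0% and 98.5% of them. Of 200 unchanged lists, 4.5% were called standing apart. These lists were drawn at random from unigenes simulated independently, so the rate does not cover lists that hold near-identical unigenes. Alternatives covered scaling, the filter, the number of reads added, a 4-fold rule, intervals that exclude a ratio of 1, summing by protein match, RPKM in place of counts, and a length of at least 500 bases. Alternatives on the later part of the table (32092 compared unigenes) and on stricter list members were added after the data were seen.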

Results

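The series measured messenger RNA in tobacco (Nicotiana tabacum) seedlings by sequencing. Seedlings were grown for 20 days on standard medium, and the treated ones were then moved to a medium low in potassium, a nutrient that plants take up as an ion and use for osmotic balance and enzyme activity. There was 1 control library and 1 low potassium library. The label of the treated library names 6, 12 and 24 h of treatment together, so its values are read as a mixture of early times and not as a time course. The library totals behind the deposited normalization were 54827386 control reads and 43887023 low potassium reads. The expression table held 97.45% and 96.92% of them, over 65535 unigenes (assembled transcripts) of 300.0 to 13178 bases. A total of 64727 unigenes had at least 20 reads over both libraries and were compared. With 1 library per group, no difference below has a replicate check, and the 95% intervals of the ratios cover counting error only. Where a fold computed from the reads is printed without an interval, its interval lay within 20% of the value.

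The comparison addressed which transcripts differ early after the move to low potassium medium. Effects of the move itself and of low potassium cannot be told apart, for higher or for lower transcripts. Most transcripts were at similar levels in both libraries: 56678 of the 64727 unigenes (87.6%) lay within 2-fold of each other. In the low potassium library 3224 unigenes were at least 2-fold higher and 4825 at least 2-fold lower. Transcripts of heat shock proteins, phenylpropanoid enzymes, histones, extensins and nicotine synthesis stood out on the higher side. Transcripts of AP2/ERF and WRKY transcription factors, of the abscisic acid list (which takes in protein phosphatases 2C) and of receptor kinases stood out on the lower side. The lower side held 59.95% of the unigenes at least 2-fold apart, and 81.3% of those at least 4-fold apart, where 434 were higher and 1889 lower. This split depends on the extent of the expression table, which ends at contig 74379: among the 32092 compared unigenes in the later part of the table, 2073 were higher and 2365 lower. When unigenes with the same best protein match were summed, 1202 matches were higher and 1361 lower.

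Among transcripts with a protein description, those with the highest ratios in the low potassium library were mostly heat shock proteins, chaperones that bind unfolded proteins, and oxidases of phenols. Catechol oxidase B (contig_66169) had 2 control reads and 263 low potassium reads, a ratio of 164 (95% interval 45.0 to 1364). Polyphenol oxidase (contig_39455) was 56.9-fold higher (46.5 to 70.4). Heat shock protein 82 (contig_72759) was 84.8-fold higher (57.7 to 130.1), heat shock protein 83 (contig_68919) 62.0-fold (51.5 to 75.3), and a cytosolic class II small heat shock protein (contig_62800) 71.1-fold (53.8 to 96.0). A heat shock cognate 70 kDa protein (contig_45874) was 25.9-fold higher, and a mitochondrial small heat shock protein (contig_47240) 20.4-fold (13.95 to 31.1). A putative auxin:hydrogen symporter (contig_2109) was 17.0-fold higher (11.7 to 25.7), a putative IAA-amino acid hydrolase (contig_73435), an enzyme type that frees auxin from conjugates, 16.2-fold (7.94 to 38.6), and a peroxidase (contig_45062) 13.3-fold (7.16 to 27.4). The remaining members of the 12 highest were a putative glycosyltransferase (contig_70678), 15.2-fold higher, and a protein described as JHL06B08.4 (contig_30470), 23.0-fold higher (13.2 to 43.8).

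The 12 lowest ratios belonged, with 1 exception, to transcription factors of the AP2/ERF family, which includes the DREB and CBF factors known from cold and drought responses. A CBF/DREB-like factor (contig_14696) was 161-fold lower in the low potassium library (95% interval 84.4 to 352), with 1806 control reads against 9. A C-repeat binding factor (contig_14695) was 139-fold lower (73.2 to 305). Wound-responsive AP2 like factor 1 (contig_4259) was 79.5-fold lower (61.7 to 104), a TINY-like protein (contig_4120) 79.1-fold (56.8 to 114), DREB3 (contig_6904) 69.1-fold (48.3 to 103), DREB4 (contig_2186) 53.4-fold (44.8 to 64.1), a putative DREB1B (contig_7261) 53.4-fold (37.0 to 79.9) and wound-responsive AP2 like factor 2 (contig_6096) 42.7-fold (33.2 to 56.0). Of 3 unigenes described only as AP2/ERF domain factors, contig_10257 was 108-fold lower (36.8 to 528) and contig_44662 70.04-fold lower (27.1 to 259). The last of these, contig_56400, had 200 control reads and 0 low potassium reads, which makes it at least 53.4-fold lower against a floor of 3 reads in the low potassium library. The exception was an avirulence-like protein (contig_2245), 79.6-fold lower (65.8 to 97.3).

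Potassium channels and transporters, the proteins that move the ion the treatment withheld, showed no common shift. Of 91 measured unigenes, 2 were at least 2-fold higher, 6 at least 2-fold lower and 83 within 2-fold. Their median log2 ratio of 0.09 lay at percentile 51.9 among 10000 random lists of the same size and expression. Both unigenes that were higher had few reads: potassium channel NKT2 (contig_30903) was 2.67-fold higher (1.58 to 4.65) and a sodium/hydrogen exchanger (contig_51220) 2.59-fold (1.86 to 3.66). Lower were unigenes of a cyclic nucleotide-gated calmodulin-binding channel, by 5.44-fold for contig_14834 and 2.08-fold for contig_14185. Putative potassium transporters, also with few reads, were lower by 6.40-fold (2.53 to 20.8) for contig_46003 and 3.84-fold (2.18 to 7.22) for contig_1414. A putative inward rectifying channel (contig_27976), with 37 control and 12 low potassium reads, was 2.47-fold lower (1.26 to 5.20). With 10 reads added it was less than 2-fold lower (log2 ratio -0.77). The most abundant members lay close to equality: a channel beta-subunit (contig_3903) was 1.06-fold higher, a potassium transporter (contig_14706) 1.37-fold higher, and 2 cyclic nucleotide-gated channels 1.11-fold higher (contig_14745) and 1.06-fold lower (contig_5340). High-affinity potassium transporters, a class known to respond to potassium shortage in other plants, were looked up after the values were seen. Of 4 unigenes matching the tobacco high-affinity potassium transporter protein 1, contig_11213 was 1.57-fold higher (1.47 to 1.67), contig_7088 1.40-fold (1.20 to 1.63) and contig_36729 1.19-fold (1.03 to 1.39), while contig_28385 had a ratio of 1.14 (0.950 to 1.36). A unigene matching the Nicotiana rustica protein (contig_20301) was 1.43-fold higher (1.29 to 1.58). Of 3 unigenes matching a pepper transporter, contig_13168 was 1.13-fold higher (1.07 to 1.20), and the intervals of contig_46816 and contig_51364 included a ratio of 1. The 1 unigene described as HAK5 (contig_30502), a fragment of 323 bases aligned over 27 residues, had a ratio of 1.23 (0.995 to 1.52). The median log2 ratio of all compared unigenes was itself 0.08, and TMM factors moved every log2 ratio by -0.08. The smallest of these folds therefore depend on the scaling chosen.

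WRKY transcription factors, a family known from defence and stress responses, were lower as a group in the low potassium library. Of 66 unigenes, 29 were at least 2-fold lower and 2 at least 2-fold higher, with a median log2 ratio of -0.76 at percentile 0. WRKY transcription factor-30 (contig_6446) was 28.3-fold lower (22.2 to 36.5) and a WRKYd factor (contig_5062) 26.6-fold (21.7 to 32.9), while a putative WRKY factor (contig_60871) was 2.67-fold higher (1.85 to 3.89). In the ethylene list, which includes the ERF factors, 47 of 141 unigenes were lower and 11 higher (median -0.38, percentile 0). The higher ones included an ethylene-responsive transcriptional coactivator (contig_5546), 9.63-fold higher, and ACC oxidase (contig_47220), the enzyme of the last step of ethylene synthesis, 5.25-fold higher. Transcripts named for rapid elicitation by a pathogen signal in tobacco cells, a list made after the values were seen, moved the same way: 42 of 61 were lower and 2 higher (median -1.89). Lists of MYB, NAC and basic helix-loop-helix factors did not stand apart. Their medians were 0.13 (percentile 76.1, 5 of 56 higher and 7 lower), 0.14 (70.3, 3 of 21 higher and 4 lower) and 0.21 (88.6, 0 of 25 higher and 2 lower). Single members differed widely, from a MYB factor (contig_18824) 10.4-fold higher (6.97 to 16.2) to a basic helix-loop-helix protein (contig_30700) 36.0-fold lower (9.69 to 302).

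**Figure D1:**
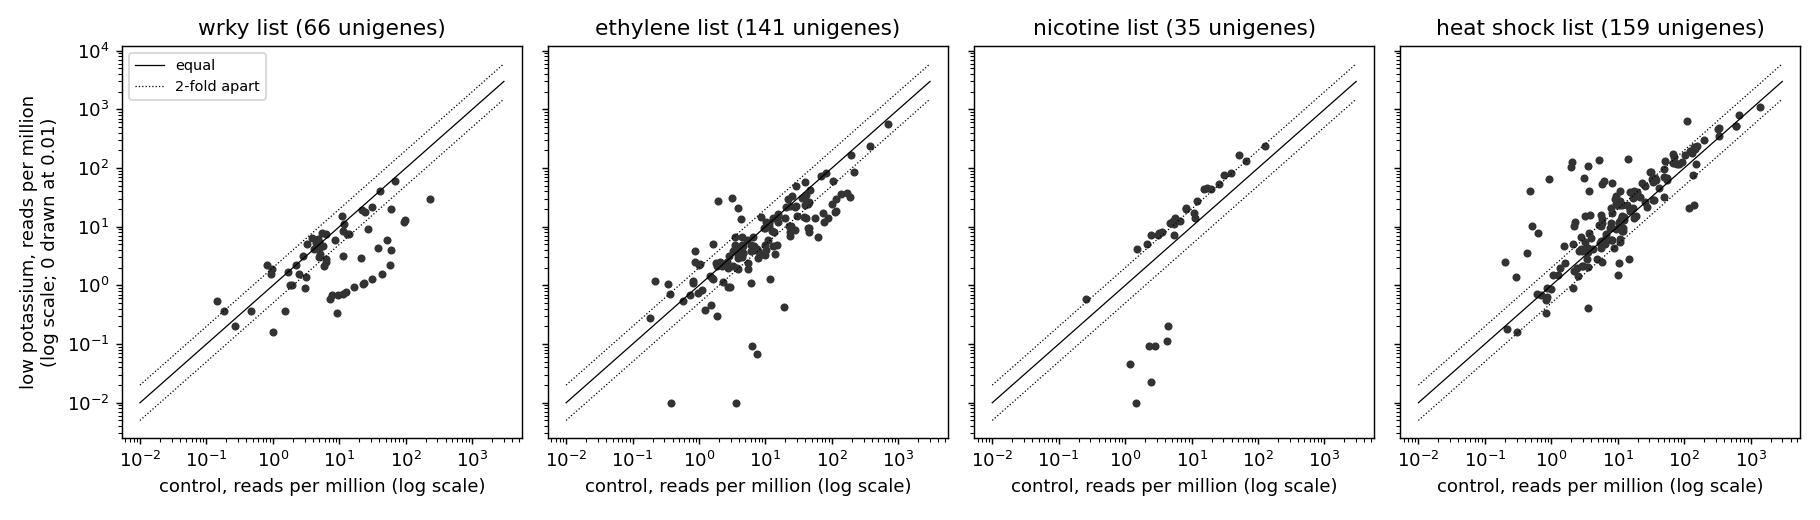
Reads scaled to the library total (RPM) in the control library (horizontal, log scale) and the low potassium library (vertical, log scale) for the unigenes of 4 gene lists, 1 point per unigene, with values of 0 drawn at 0.01. Of the points outside the dotted 2-fold lines, 29 of 31 WRKY unigenes lie below, 51 of 61 heat shock unigenes lie above, and the nicotine list separates into 22 above and 7 far below.

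Several hormone and signalling groups were also lower. In the abscisic acid list, a hormone of water stress, 20 of 75 unigenes were lower and 2 higher (median -0.22, percentile 0). Protein phosphatases 2C led it, with contig_1288 26.4-fold lower (22.0 to 31.9) and contig_8213 12.6-fold lower. Some members of that family act in abscisic acid signalling, and the descriptions do not say whether these do. In the jasmonate list, the wound hormone, 23 of 91 unigenes were lower and 2 higher. A lipoxygenase (contig_2055), of an enzyme class that starts jasmonate synthesis, was 24.8-fold lower and a jasmonate ZIM domain repressor (contig_44040) 20.3-fold (11.4 to 39.7). The jasmonate median was -0.04 (percentile 1.10), with 66 unigenes within 2-fold, and no longer stood apart when unigenes of the same match were summed (0.02, percentile 11.6) or with at least 100 reads (percentile 3.55). Gibberellin and cytokinin genes had 15 of 66 unigenes lower and 3 higher (median -0.13, percentile 0.02). Cytokinin-regulated kinase 1 (contig_11644) was 12.0-fold lower (9.78 to 14.8), and gibberellin 3beta-hydroxylase (contig_61030), which makes active gibberellin, 6.11-fold higher (4.94 to 7.63). Receptor-like and MAP kinases had 42 of 205 unigenes lower and 6 higher (median -0.06, percentile 0.01), among them a membrane located receptor-like protein (contig_18779), 40.3-fold lower (31.6 to 52.4), and a putative receptor-like protein kinase (contig_45913), 2.57-fold higher (1.91 to 3.51). Calcium signalling genes did not stand apart (median 0.06, percentile 31.4). Of 137 unigenes 17 were lower and 8 higher, including the calcium-binding protein CML38 (contig_13561), 15.5-fold lower (11.4 to 21.4), a calcium-dependent protein kinase (contig_7730), 3.36-fold lower, and CBL-interacting protein kinase 11 (contig_50060), 2.499-fold higher (1.53 to 4.17). Auxin genes did not either (median 0.10, percentile 65.4, with 13 of 196 higher and 11 lower), although IAA29 (contig_24113) was 5.11-fold lower (4.09 to 6.45) and a second putative auxin:hydrogen symporter (contig_5567) 3.20-fold higher.

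Nicotine synthesis transcripts, which tobacco is known to express in roots, were higher together. Of 35 unigenes in the nicotine list, 22 were at least 2-fold higher and 7 at least 2-fold lower, and the median log2 ratio was 1.15 (percentile 100). Ornithine decarboxylase (contig_12093) was 3.19-fold higher and a berberine bridge enzyme like protein (contig_9638) 2.91-fold higher. The 7 lower members were all nicotine uptake permeases, which pulled the list's mean to -0.05. Among the 21 unigenes of synthesis enzymes, all were higher and 18 by at least 2-fold, with a median of 1.23. The list of root transcripts was also higher, with 12 of 38 unigenes at least 2-fold higher and 0 lower (median 0.54, percentile 100). It consisted mostly of extensins, cell wall proteins, such as cysteine-rich extensin-like protein-4 (contig_30788), 9.43-fold higher (7.81 to 11.5). A list of 11 root transcripts without extensins, made after the values were seen and including SHORT-ROOT proteins and RB7 aquaporins, had a median of 0.33 (percentile 93.1), and its summed reads were 1.22-fold higher (1.16 to 1.28). Transcripts of photosynthesis, which mark green tissue, took 9.53% of the control reads and 8.92% of the low potassium reads. Their median of -0.07 lay at percentile 0.22, yet 135 of 141 unigenes were within 2-fold, 4 being higher and 2 lower. In the polyamine list, whose pathway shares ornithine decarboxylase with nicotine, the median was 0.27 (percentile 99.8), with 3 of 37 higher and 5 lower. Arginine decarboxylase (contig_4219), the alternative entry into that pathway, was 3.19-fold lower, and polyamine oxidase (contig_3736) 3.27-fold lower.

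Heat shock proteins and chaperones had 51 of 159 unigenes at least 2-fold higher and 10 lower (median 0.51, percentile 100). The lower ones included a dnaJ chaperone (contig_13298), 6.78-fold lower (5.25 to 8.89), and a heat shock protein binding protein (contig_7148), 5.89-fold lower. Phenylpropanoid enzymes, which make lignin and flavonoids, had 39 of 135 higher and 3 lower (median 0.63, percentile 100). Putative spermidine hydroxycinnamoyl transferase (contig_6100) was 6.00-fold higher and a putative dihydroflavonol reductase (contig_21619) 2.93-fold lower. Histone transcripts had a median of 0.76 (percentile 100), with 0 of 99 lower and a number at least 2-fold higher that depends on scaling, 17 in the main setting and 8 with TMM factors. Among them were histone H2B unigenes, 2.76-fold (2.00 to 3.85; contig_42104) and 2.33-fold higher (1.89 to 2.89; contig_19882). Ribosomal protein transcripts shifted slightly and evenly: the median was 0.20 (percentile 100), with 1 of 455 higher and 3 lower. One of these, a chloroplast-specific ribosomal protein (contig_4013), was 3.22-fold lower. The list of glycolytic and fermentation enzymes had a median of 0.25 (percentile 100), with 9 of 188 higher and 2 lower. By name it took in short chain alcohol dehydrogenases, whose descriptions do not give a role in fermentation. Members higher were a putative short chain alcohol dehydrogenase (contig_60445), 3.70-fold (3.05 to 4.50), and a pyruvate kinase (contig_42472), an enzyme that needs potassium for activity, 2.22-fold (1.65 to 3.01), and a short chain alcohol dehydrogenase (contig_6123) was 2.63-fold lower. Proton pumps and aquaporins (water channels) had 5 of 63 higher and 0 lower (median 0.33, percentile 100), led by aquaporins 7.89-fold (6.27 to 10.04; contig_57043) and 7.80-fold higher (contig_16098).

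**Figure D2:**
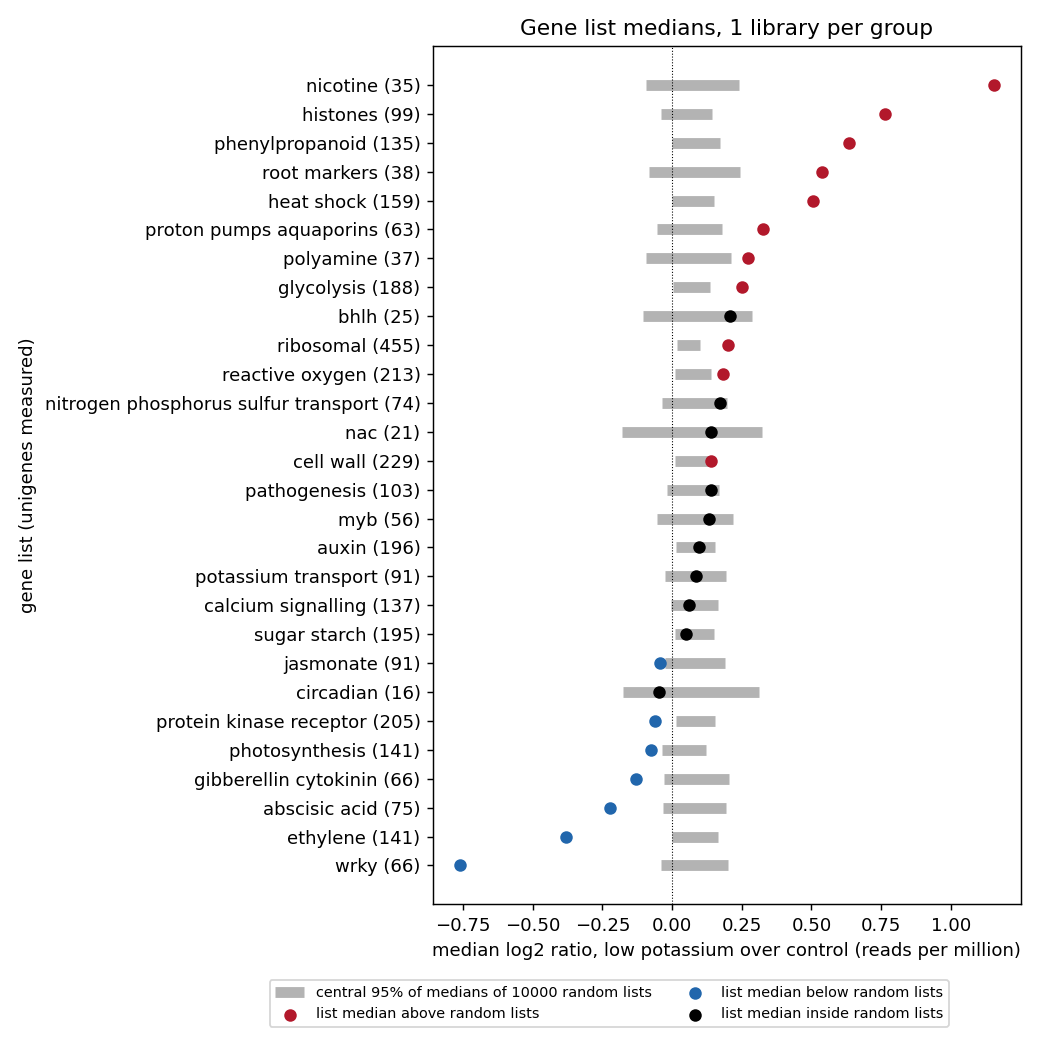
Median log2 ratio of low potassium over control (horizontal) for the 28 gene lists (vertical, with the number of unigenes measured), 1 library per group. Grey bars span the central 95% of the medians of 10000 random lists of the same size and expression; 11 lists lie above their bar, 7 below and 10 inside.

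Reactive oxygen genes had 33 of 213 unigenes higher and 16 lower (median 0.18, percentile 99.9). A cationic peroxidase (contig_52624) was 13.4-fold higher (6.52 to 32.1), whereas a chloroplastic copper-zinc superoxide dismutase (contig_15707) was 3.81-fold lower and a glutathione peroxidase (contig_11072) 3.78-fold lower. Cell wall genes went both ways, with 37 of 229 higher and 31 lower. Expansin L (contig_45985), of a family that loosens walls, was 9.47-fold higher (5.85 to 16.2) and an arabinogalactan-protein (contig_48830) 9.57-fold (7.05 to 13.3). A cellulose synthase subunit (contig_444) was 10.2-fold lower and the xyloglucan enzyme XTH9 (contig_624) 9.52-fold lower. The cell wall median of 0.14 lay at percentile 97.7, and at percentile 95.1 with at least 100 reads required. Pathogenesis-related proteins did not stand apart (median 0.14, percentile 90.1, with 23 of 103 higher and 12 lower). Pathogenesis-related protein R (contig_64589) was 10.6-fold higher (6.56 to 18.0) and a type II proteinase inhibitor (contig_34479) 9.70-fold, while a harpin inducing protein (contig_15076) was 6.74-fold lower. Transporters and enzymes of nitrogen, phosphorus and sulfur had 17 of 74 higher and 4 lower (median 0.17, percentile 93.7). A putative oligopeptide transporter (contig_14514) was 4.73-fold higher and a putative sulfate transporter (contig_67505) 3.59-fold higher (2.36 to 5.59), while a sulfate transporter-like protein (contig_35277) was 2.35-fold lower and nitrate reductase (contig_325), the first enzyme of nitrate assimilation, 2.23-fold lower. Sugar and starch genes had 17 of 195 higher and 27 lower, with a trehalose-6-phosphate synthase (contig_17644) 20.3-fold lower, a beta-amylase (contig_7348), which degrades starch, 5.06-fold lower and an invertase inhibitor (contig_10774) 4.05-fold higher. Their median was 0.05 (percentile 18.4), and 0.17 (percentile 96.2) when unigenes of the same match were summed. TMM scaling, which moved every log2 ratio by -0.08, put the sugar median at -0.03 and the calcium median at -0.01, with percentiles of 19.5 and 32.2. The 16 clock unigenes had a median of -0.05 (percentile 15.7), with 4 lower and 0 higher, and stood apart when summed by match (-0.22, percentile 2.18). The clock coupling factor ZGT (contig_2863) was 13.04-fold lower and an EARLY flowering 4 protein (contig_31596) 3.68-fold lower (2.74 to 5.02). Median and mean had opposite signs for the nicotine, calcium, NAC, basic helix-loop-helix and sugar lists.

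The authors' deposited table of differing contigs, made with a false discovery rate of 0.05, listed 1033 contigs, 308 of them higher and 725 lower in the low potassium library. Of these, 1008 were in the expression table, and all 1008 had the same direction and were at least 2-fold apart in the ratios computed here, which follows from their selection on the RPKM of the same reads. The authors' test compares the values of these 2 libraries and not the conditions. By the RPKM values of the authors' deposited table, the largest differences on the higher side were a class III peroxidase (238-fold), a small heat shock protein (195-fold), an unannotated contig (102-fold), heat shock protein 82 (84.8-fold) and a non-specific lipid-transfer protein (72.8-fold). On the lower side the authors' deposited table gave wound-responsive AP2 like factor 2 (231-fold and 186-fold for separate contigs), the CBF/DREB-like factor (161-fold), the C-repeat binding factor (139-fold) and an uncharacterized protein (109-fold). It also listed 2 contigs at 0 RPKM in the low potassium library, for which no fold was given, described as wound-responsive AP2 like factor 2 and avirulence-like protein 1. The folds from the authors' RPKM carry no interval, and the largest rest on very low values. In the control the class III peroxidase had 0.094 RPKM and the small heat shock protein 0.087. The 231-fold difference rests on 0.1075 RPKM in the low potassium library.

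**Figure D3:**
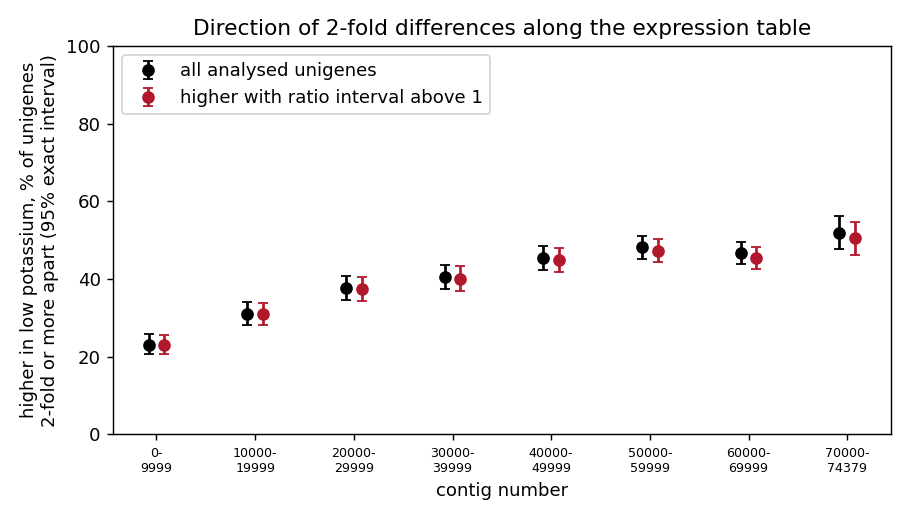
Share of unigenes higher in the low potassium library (vertical, percent of unigenes at least 2-fold apart, with exact 95% binomial intervals) along the contig numbers of the expression table (horizontal), for all analysed unigenes (black) and counting as higher only those whose ratio interval lay above 1 (red). The black share is 23.1% in the first group of contigs and 51.9% in the last.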

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

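The tests in this part were chosen after the results they bear on had been seen.

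Reads in the library totals but not in the expression table were not part of any comparison, and relative to the totals they were 1.208 times as frequent in the low potassium library as in the control (95% interval 1.205 to 1.211). Whether all of them lie on later contigs was not tested. Of the 25 contigs of the authors' deposited table that lie outside the expression table, 25 were higher in the low potassium library, and 10 of them are described as heat shock proteins. Both signals lie in data that the comparisons did not use. A candidate explanation is that contig numbers follow abundance in the control, so that ending the table at a contig number removes transcripts scarce in the control. The values needed are there: among unigenes at least 2-fold apart, the share higher in the low potassium library was 23.11% (20.65 to 25.72) in the first group of contigs and 51.93% (47.64 to 56.21) in the last. Shallow counts at late contigs are argued against as the whole cause: in the last group 274 unigenes were higher with a ratio interval above 1, which is 50.46% (46.17 to 54.75) of its 543 unigenes apart even if all others are taken as lower. A minimum of 200 reads had been set as this test before its result was seen, and gave 22.48% in the first group and 73.47% in the last. It was replaced after that, because late contigs, with a median of 56 control reads, reach the minimum more easily when high in low potassium. No biological explanation was tested for the order of contigs.

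WRKY and AP2/ERF transcripts were lower in the low potassium library. A scaling difference between the libraries would move all unigenes alike. It is argued against for the WRKY list, whose median of -0.761 lay at percentile 0, against 0.082 for matched random lists. The WRKY median of -0.837 with TMM factors follows from their shift of -0.08 and tests nothing further. A different hour of harvest stays open: 25% of the 16 clock unigenes were at least 2-fold apart, between the bounds set for either reading. Those bounds could hardly decide it. They were set after the data were seen, and the lower one lay under the share of all compared unigenes 2-fold apart (8049 of 64727). Summed by protein match the clock median was -0.222 (percentile 2.18), while the most abundant GIGANTEA unigene was within 1.01-fold and PSEUDO-RESPONSE REGULATOR 7 within 1.17-fold. Handling or wounding of the control seedlings cannot be told apart from an effect of low potassium, since the list of rapidly elicited transcripts had a median of -1.888 and either could give that with 1 library per group. Effects of potassium shortage itself and of the move of treated seedlings to new medium stay among the open explanations, untested for the same reason.

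Nicotine synthesis transcripts were higher in the low potassium library. If reads were split between near-identical unigenes, a rise in some copies would come with a fall in others. All 21 enzyme unigenes were higher, with a smallest log2 ratio of 0.911, which argues against this for these unigenes. The 13 enzymes summed per protein match had a median log2 ratio of 1.199. That adds nothing, since sums of higher unigenes are higher too. A larger share of root in that library stays open, because the values of the 38 unigenes in the root list point both ways: their median of 0.538 (95% interval 0.256 to 0.887) lay below the lower quartile of the nicotine enzymes, 1.09, while their summed reads, on the log2 scale 1.214, lay above it. Of these 38 unigenes, 22 had a ratio interval below that quartile and 8 had one above it. Unlike the ratio intervals, the 95% interval of the median is an interval over unigenes, some of which can be near-identical. It holds nothing of the spread between plants. The extensins, with 12 of 31 unigenes at least 2-fold higher and 19 within 2-fold, had a median of 0.553 and a mean of 1.01. Their direction and that of the photosynthesis list (median -0.074, percentile 0.22) go with a larger share of root. By their medians, neither the extensins nor the 11 root transcripts of the list without extensins (0.328) show a rise of the size of the nicotine enzymes. A response to low potassium or to the move to new medium, and a difference between the batches of seedlings that the labels do not describe, stay open too and were not tested.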

How the results depend on the processing

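The later part of the table and the stricter list members were chosen after seeing the data. The counts of 3224 higher and 4825 lower unigenes stayed within 1.5 times under TMM factors, size factors, both filters, 10 reads added, RPKM, the 500-base minimum and the interval rule, with 2323 to 3348 higher and 3261 to 5256 lower. They moved to 434 and 1889 with the 4-fold rule, to 1202 and 1361 when summed by protein match, and to 2073 and 2365 in the later part of the table; the last 2 compare fewer units by construction. Of the 28 list medians, 28 kept their side of the percentile limits without a filter and with 10 reads added. All 28 did so with TMM factors too. That says nothing on stability, because these factors shift the listed and the random medians alike. Leaving out the filter was a weak check too, since it hardly changed the members (jasmonate from 91 to 93 unigenes). With at least 100 reads, jasmonate (-0.009, percentile 3.55) and cell wall (0.135, percentile 95.1) no longer stood apart. Summed by protein match, jasmonate (0.022) and cell wall (0.18, percentile 97.1) no longer stood apart and the clock list did (-0.22, percentile 2.18). A root list without extensins did not stand apart (0.33); the cause of these changes of call was not tested. Heat shock proteins alone had a median of 0.99, nicotine enzymes alone 1.23, jasmonate without channels -0.05 and auxin without the resistance protein 0.10, each on the same side of the limits. For the first 2 this says nothing on stability. Their 65 and 21 unigenes leave out every member of the full lists that was at least 2-fold lower. The direction of the 1008 contigs shared with the authors' deposited table says nothing on stability, since they were selected on the same RPKM values and have at least 225 reads.

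Of the 112 unigenes selected by the naming rule, 112 kept their direction with TMM factors, with 10 reads added and with RPKM. Under these settings 10, 9 and 1 of them left their counting interval. The kept direction says little on stability, since 108 of the 112 were at least 2-fold apart and TMM moved log2 ratios by only -0.08. The RPKM were made from the same reads. Of the 108 at least 2-fold apart, 108, 103 and 107 stayed so. No paired analysis was possible because there is 1 library per group. Depth limits the ratios of transcripts with few reads in either library, such as catechol oxidase B, whose interval runs from 45.0 to 1364.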

Other observations

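The gene groups in this part were put together after the data were seen. Lipid transfer proteins, small secreted proteins that bind lipids, were higher as a group in the low potassium library. Of 34 unigenes 18 were at least 2-fold higher and 1 was lower, with a median log2 ratio of 1.05 (percentile 100), and of 0.64 over 17 protein matches after summing. The most abundant had 10516 control reads and 36178 low potassium reads, 4.30-fold higher (95% interval 4.21 to 4.39). Another, with 54 and 3147 reads, was 72.8-fold higher (55.7 to 97.1). DREB, CBF and wound-responsive AP2 factors were lower, with 32 of 48 unigenes lower and 2 higher. Their median was -4.45, or -4.28 with the 4 unigenes at 0 low potassium reads set at their bound. After summing, the median over 19 protein matches was -3.46, with 12 lower and 2 higher. The group did not move as a whole: a DREB2a factor with 4489 control and 2859 low potassium reads was 1.26-fold lower (1.20 to 1.32), and a putative TINY factor was 2.59-fold higher (2.32 to 2.89).

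Nicotine uptake permeases, membrane proteins that import nicotine, separated into 2 groups. Of 12 unigenes, 7 had 66 to 243 control reads but only 0 to 9 low potassium reads. The other 5 were higher, from 1.29-fold (1.15 to 1.44) to 2.43-fold (1.94 to 3.07). The 2 unigenes with 100% identity to the described permeases were 1.34-fold (1.14 to 1.58) and 1.58-fold (1.41 to 1.76) higher, and the 7 that were nearly absent had identities of 91.7% to 95.3% over 112 to 245 residues. Summed by protein match, both permeases lay within 2-fold.

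Unigenes whose best match was in a genus that is not a plant took 0.323% of the control reads and 0.400% of the low potassium reads.

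The p-values of the authors' deposited table were set beside 2 versions of Fisher's exact test, each comparing these 2 libraries and not the conditions. Applied to RPKM values rounded to whole numbers, 98.7% of the p-values came within 1 log10 unit of the deposited ones. Applied to the reads, 0.0992% did. The deposited calls also leave out scarce transcripts: no listed contig had a larger RPKM under 12.3, while 5535 of the 8049 unigenes at least 2-fold apart had a larger RPKM under 10. Of 1483 unigenes at least 2-fold apart with a larger RPKM of at least 20, 947 were in the deposited table.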
